A study of Mus musculus with 12 samples.

How the data were processed

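Single-nucleus RNA sequencing was done on prefrontal cortex nuclei of 12 female mouse samples, 6 after chronic social defeat stress and 6 healthy controls. Per the labels' protocols, nuclei were purified on sucrose and libraries were made with a droplet 3' kit that carries UMIs, then sequenced in paired-end mode. The submitters' processing notes name fastp and the mm10 build. The aligner, the counting tool and its use of strand are not given in the sources used here. The deposited matrix holds whole-number UMI counts per gene and nucleus, which the authors left unnormalised, with gene symbols and barcodes in separate lists. It holds 0 genes with the prefix of mitochondrially encoded genes and no nucleus above 3999 detected genes, so a filter on mitochondrial counts could not act. A second deposited table holds p-values and Bonferroni-adjusted p-values per gene and cell type label, and the authors' log2 fold changes beside the fraction of nuclei with the gene on each side. The test behind the deposited p-values, its unit of replication and its direction are not given in the sources used here.

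Barcode suffixes 12 to 23 match no sample label, so no nucleus was assigned to a group. The count tests, share tests and gene set tests planned between groups before the data were examined were therefore not run, and values per suffix are given as ranges and medians. Between suffixes, counts summed over nuclei differed by more than sampling noise in all 66 pairs (lowest chi-square per degree of freedom 5.65), so no library looked deposited more than once.

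Nuclei with at least 300 detected genes were kept (33 fell below). Scrublet as built into scanpy 1.11.5, run per suffix with an expected rate of 6%, called 139 nuclei, or 0.142%. Its automatic threshold has not worked at so low a share, so doublets beyond these must be assumed to remain. The called nuclei were left out, as were 774 nuclei in clusters treated as mixed, which left 97278. Such clusters had markers of 2 classes or were glial clusters with at least 2 times the UMIs of the largest cluster of their class. Counts were scaled to 10000 per nucleus and log-transformed, 3000 variable genes and 40 principal components were used, and Leiden clustering of a shared-neighbour graph (igraph 0.11.9, 20 neighbours, resolution 1) gave 44 clusters. Clusters were named from markers fixed before the data were examined, but the scoring rule that turns markers into names was adjusted over several rounds after the clusters had been seen, and only its last form was kept. In that form a name needed at least 3 markers, counted as at least 2-fold above the other nuclei for classes other than excitatory neurons, and clusters that met no rule stayed unnamed. The shares of the classes depend on this choice. Values of a class are its summed counts scaled to an equal total (CPM), and the share of its nuclei with a UMI. A gene's highest class was sought among classes with at least 20 nuclei in each library, and is given with the number of libraries that show the same order, with no p-value. Because background transcripts weigh more in the CPM of shallow classes, the order was also taken from UMIs per nucleus for genes of the corticosteroid response, a check chosen after the data were seen.

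Labels of the deposited table were tied to the class with the smallest root mean square difference between the mean of its percentages and the detection here. Membership of 28 gene lists fixed before the data were examined was tested per label and side with a one-sided Fisher's exact test. The way of tying labels to classes, this test and its background were chosen after the data were seen, since the planned tests could not be run. The background was genes in at least 10% of nuclei of the class, a list needed 3 members in it, and p-values were adjusted by Benjamini-Hochberg over 262 tests. Genes are not independent replicates, so these p-values describe the lists only. The result of 1 list is not reported here. Recurrence was compared with 1000 random draws of lists of the same sizes. Simulated lists of the same sizes had 10 oxidative phosphorylation genes planted on the first side of Ast, Mic and Oli. With all 23736 genes, 60 of 60 planted memberships were recovered and 0 of 5180 other tests were called. Recovery of other lists, or of calls that rest on fewer members, was not simulated. From percentages drawn from their own classes, 8 of 8 labels were matched back, which covers counting error only.

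The rule for named genes was set before the data were examined. Its parts that could be applied were the 10 genes with the smallest p-values in the authors' deposited table, without predicted genes named by Gm or Rik symbols, Xist as a label check, and Fkbp5, Sgk1, Nr3c1, Bdnf, Gfap and Fos. Its parts that rank genes by a test between groups could not be applied, so all other genes named, list members included, were chosen after their values were seen. Coordinates come from GENCODE release M21 on the same build. Exact permutation tests and correlations used scipy 1.17.1 and adjustment used statsmodels 0.14.6. Alternatives planned and added after the data were seen were a coarser clustering, all deposited barcodes, other denominators, each library left out, a minimum of 1000 UMIs, removal of the highest 5% of doublet scores and other backgrounds.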

Results

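Nuclei were isolated from frozen prefrontal cortex of female mice and their RNA was counted by droplet single-nucleus RNA sequencing. The labels describe 12 samples in 2 groups of 6. One group had gone through chronic social defeat stress, a procedure in which repeated defeat by an aggressor induces depression-like behaviour, and the other was the healthy control. The deposited counts form a single matrix of 98224 nuclei and 23736 genes, counted as unique molecular identifiers (UMIs). Its barcodes carry 12 suffixes, numbered 12 to 23, and no suffix matches a sample label. Each suffix was taken as 1 library whose group is unknown, which the labels do not state, so no value from the matrix was compared between stressed and control mice. Libraries held 7123 to 9637 nuclei (median 8006) and 23619092 to 31090878 UMIs. The median nucleus had 2539 to 3274 UMIs and 1448 to 1830 detected genes, depending on the library. The female label could be checked: Xist, the RNA that coats the inactive X chromosome, lay between 1467 and 2007 CPM, the count of a gene scaled to an equal total for each sum of nuclei, in the 12 libraries, while the Y-linked gene Uty had 0 to 4 UMIs in each.

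Excitatory neurons made up most of the tissue sampled. Clusters with excitatory neuron markers held 53015 of the nuclei kept, or 54.5% when pooled, and their share per library ran from 46.7% (95% exact binomial interval 45.6 to 47.7) to 61.5% (60.4 to 62.6). Inhibitory-neuron-like nuclei had a median share of 10.8%, with 11 libraries between 9.28% and 13.1% and the library of suffix 14 at 28.1% (27.2 to 29.1). Astrocyte-like nuclei had a median of 8.43% (range 5.80 to 9.81), oligodendrocyte-like nuclei 7.80% (4.95 to 13.7) and microglia-like nuclei 5.26% (4.04 to 7.31). Oligodendrocyte-precursor-like (OPC-like) nuclei followed at 2.58%, fibroblast-like vascular leptomeningeal nuclei at 2.14%, endothelial-like nuclei at 1.78% and mural-like nuclei, the pericytes and smooth muscle of vessels, at 0.726%. Clusters that met no marker rule held 3661 nuclei and a median of 2.83% (1.40 to 8.85). The largest of them had 2369 nuclei and a median of 843 UMIs. Its leading genes included the ribosomal protein genes Rps27a, Rps23 and Rpl32, beside Cst3, Pcp4 and Actb. Intervals here and below cover counting error only. Glial and vascular nuclei were shallow, with a median of 942 UMIs in oligodendrocyte-like and 801 in microglia-like nuclei against 4202 in excitatory-neuron-like nuclei, and with only nuclei of at least 1000 UMIs the pooled oligodendrocyte-like share moved from 7.98% to 4.04% and the microglia-like share from 5.35% to 1.42%.

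**Figure D1:**
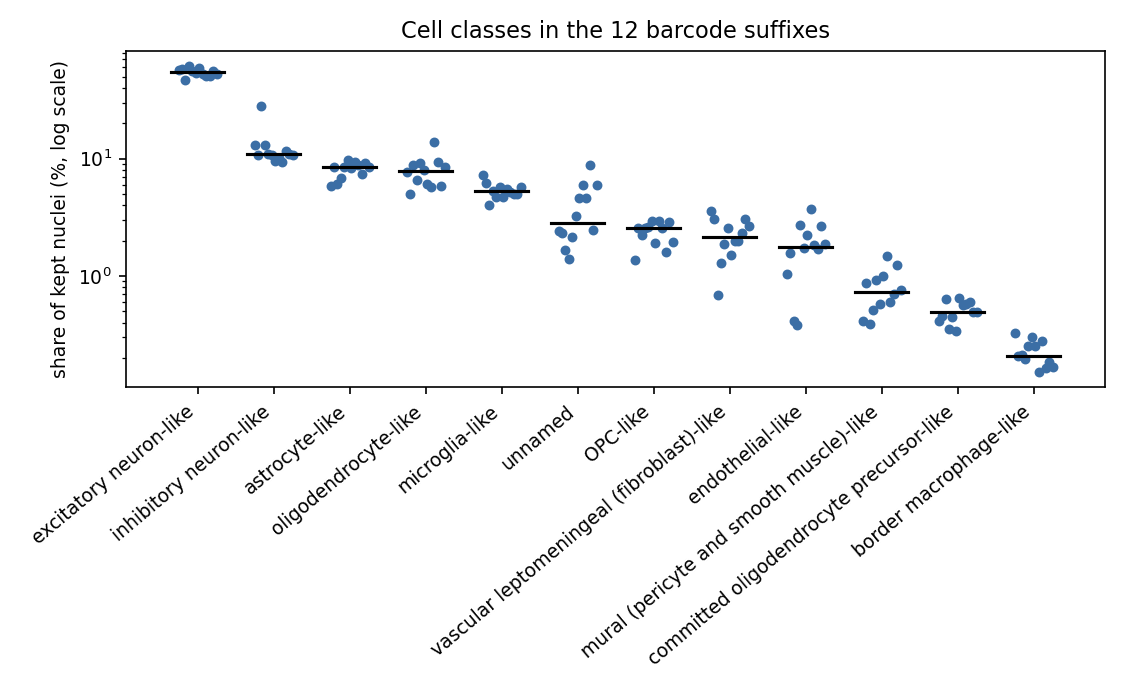
Share of kept nuclei (%, logarithmic axis) for each cell class. Each point is 1 barcode suffix, drawn from suffix 12 on the left to 23 on the right within a class, and the bar is the median of the 12. The inhibitory-neuron-like share stands at 28.1% for suffix 14 and at most 13.1% for the others.

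Among excitatory-neuron-like nuclei, those with markers of layer 2/3 intratelencephalic neurons had a median share of 33.2% per library (21.3 to 37.4), and layer 6 corticothalamic-like nuclei 15.8% (11.4 to 19.3). Layer 5 extratelencephalic-like nuclei, the neurons that project to subcortical targets, had a median of 6.48%, but ranged from 0.184% (interval 0.0794 to 0.362) at suffix 12 to 8.83% (8.04 to 9.67) at suffix 13. A median of 33.7% of excitatory-neuron-like nuclei met no layer rule. Among inhibitory-neuron-like nuclei, Pvalb-like interneurons had a median share of 31.7%, Sst-like 23.8% and Lamp5-like 16.6%. All 3 shares were lowest at suffix 14, at 12.3%, 9.20% and 4.64%, where 73.9% of inhibitory-neuron-like nuclei had no subclass name.

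Genes of the corticosteroid response differed in level between cell classes within the same libraries. For Nr3c1, the glucocorticoid receptor, no order of classes is read, because CPM and UMIs per nucleus gave different orders: it had 294 CPM and 0.440 UMIs per nucleus in endothelial-like, 234 and 0.196 in microglia-like, 117 and 0.535 in excitatory-neuron-like and 80.6 and 0.241 in inhibitory-neuron-like nuclei. The orders given for the other genes here were the same by UMIs per nucleus, but the class next to the highest was not always the same. By UMIs per nucleus, inhibitory-neuron-like nuclei came next for Sgk1 and Crhr1. Sgk1 had 0.436 there, against 0.465 in oligodendrocyte-like and 0.408 in OPC-like nuclei. Crhr1 had 0.0382 there, against 0.172 in excitatory-neuron-like and 0.0214 in endothelial-like nuclei. Nr3c2, the mineralocorticoid receptor, reached 910 CPM in fibroblast-like nuclei against 306 in inhibitory-neuron-like nuclei, higher in 12 of 12 libraries (1.57-fold to 3.96-fold). Fkbp5, a co-chaperone induced by glucocorticoids, stood at 848 CPM in fibroblast-like and 595 in microglia-like nuclei, against 167 in astrocyte-like, 37.5 in excitatory-neuron-like and 37.5 in inhibitory-neuron-like nuclei. Its level varied between libraries, from 123 to 1160 in microglia-like and from 11.9 to 308 in astrocyte-like nuclei. Sgk1, a kinase induced by the same hormones, was highest in oligodendrocyte-like nuclei at 465 CPM, above OPC-like nuclei (255) in 12 of 12 libraries. Of the receptors of corticotropin-releasing hormone, Crhr1 was highest in excitatory-neuron-like nuclei at 37.6 CPM, above endothelial-like nuclei (14.3) in 11 of 12 libraries, and Crhr2 reached at most 2.07 in any class. The progesterone receptor gene Pgr was found in 20.1% of excitatory-neuron-like nuclei at 53.1 CPM, above inhibitory-neuron-like nuclei (40.7) in 11 of 12 libraries. Gfap, the intermediate filament of astrocytes, had 40.6 CPM in astrocyte-like nuclei (16.1 to 66.2 over the libraries) and 0.971 in excitatory-neuron-like nuclei.

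Some transcripts were spread over every class alike. Cck, a neuropeptide gene, was counted in 59.1% of excitatory-neuron-like nuclei, at 0.962 UMIs per nucleus, and also in 54.5% of microglia-like nuclei, at 0.820 UMIs per nucleus. Bdnf was of this kind outside excitatory neurons. Bdnf was counted in 18.5% of excitatory-neuron-like nuclei and in 7.17% of inhibitory-neuron-like, 7.21% of astrocyte-like and 6.74% of microglia-like nuclei, and Fos in 5.23% of excitatory-neuron-like and 3.11% of astrocyte-like nuclei. The shares of Bdnf outside excitatory neurons are read as background. Median depths differed from 801 to 2750 UMIs per nucleus among those 3 classes without a like difference in share. Fos is not read this way, since its share is given in astrocyte-like nuclei only.

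The comparison of control with depression, the question the series was made for, is held in the authors' deposited table of 511 gene entries under 9 cell type labels. That table gives for each gene a log2 fold change, the percentage of nuclei with the gene on each side, and a p-value, and its adjusted p is the p multiplied by the number of genes in the matrix. Its name puts control before depression, but which group its first percentage and its positive fold changes belong to is not stated in the sources used here, so the sides are called first and second. Of the entries in the authors' deposited table, 234 were higher on the first side and 277 on the second, all with an absolute log2 fold change of at least 0.25. No values per library stand beside them, and no label ties a library of the matrix to a side. They were therefore not tested against the spread between mice. Labels could be tied to cell classes: the percentages for the label Ast in the authors' deposited table matched detection in astrocyte-like nuclei with a root mean square difference of 0.221 percentage points, Mic matched microglia-like nuclei within 0.272, Oli matched oligodendrocyte-like nuclei within 0.282 and Int matched inhibitory-neuron-like nuclei within 0.581. Exn, Fib, OPC and End matched excitatory-neuron-like, fibroblast-like, OPC-like and endothelial-like nuclei within 1.99, 1.11, 1.77 and 4.06. The match of End is the least certain, since fibroblast-like nuclei came next at 6.27, and Fib had microglia-like nuclei next at 4.29. The ninth label, other, has 2 genes and was tied to no class.

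Under the label of excitatory neurons, genes induced by neuronal activity were higher on the second side. The authors' deposited table lists 35 genes under Exn, 24 of them higher on the second side. They include 4 of the 10 immediate early genes detected in at least 10% of excitatory-neuron-like nuclei, which are transcribed within minutes of stimulation, where 0.0406 would be expected by chance (one-sided Fisher's exact test, adjusted p = 2.27e-06). This call was lost when genes listed under 4 or more labels of the authors' deposited table were left out. Egr3, a zinc finger transcription factor, had a log2 fold change of -0.53 and was found in 18.5% of nuclei on the first and 32.7% on the second side in the authors' deposited table. Homer1, a postsynaptic scaffold, had -0.49 (75.6% and 82.6%), Egr1 had -0.39 (22.2% and 32.6%) and Arc, a regulator of glutamate receptor trafficking, -0.26 (13.4% and 20.1%), again in the authors' deposited table. Arc and Ntrk2, the receptor of brain-derived neurotrophic factor (-0.31, 79.5% and 82.5%), put the list of neurotrophin and plasticity genes above chance (2 of 17 members, adjusted p = 0.0272), according to the same test on the authors' deposited table. Arc belongs to both lists, so the second call is not independent of the first and adds only Ntrk2. Higher on the first side in the authors' deposited table were the nuclear RNA Malat1 (0.35) and the cell adhesion genes Tenm2 (0.28) and Lrrtm4 (0.29). Part of these counts is read as background, since UMIs per nucleus in excitatory-neuron-like and in microglia-like nuclei were 0.354 and 0.209 for Egr1, 0.359 and 0.161 for Egr3, 2.94 and 0.317 for Homer1 and 0.226 and 0.0494 for Arc. Whether the differences of Egr1 and Egr3 under Exn arose in excitatory neurons or in this background was not separated. Between libraries, detection of Egr3 in excitatory-neuron-like nuclei ran from 12.7% to 46.7%.

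The 10 named genes with the smallest p-values in the authors' deposited table had those p-values under this label. In the annotation of the mm10 genome they are Egr3 (chromosome 14, 70077203 to 70082614), Homer1 (chromosome 13, 93299635 to 93405129), Cmss1 (chromosome 16, 57302000 to 57606864) and Malat1 (chromosome 19, 5795690 to 5802672), whose p-values are printed as 0 in the authors' deposited table. Pde10a (chromosome 17, 8525372 to 8986648), Tenm2 (chromosome 11, 36006656 to 37235964), Camk1d (chromosome 2, 5293457 to 5714515), Egr1 (chromosome 18, 34859823 to 34864984) and Ntrk2 (chromosome 13, 58806569 to 59133970) follow, with AC149090.1, which was not matched to the annotation used here. All but Malat1, a long noncoding RNA, and AC149090.1 are annotated as protein-coding genes.

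Most glial and vascular labels shared a pattern of ribosomal and respiratory genes on the first side. Under Ast, 17 of the 70 cytosolic ribosomal protein genes and 11 of the 60 nuclear genes of oxidative phosphorylation in the background were higher on the first side in the authors' deposited table (adjusted p = 3.24e-14 and 1.62e-07, one-sided Fisher's exact test). Mic held 13 ribosomal and 11 respiratory genes (adjusted p = 1.62e-07 and 6.97e-07), Oli 7 and 5 (0.000838 and 0.0114) and End 6 and 3 (1.98e-05 and 0.0353), and Fib held 3 ribosomal genes (0.0487, lost with a background of genes in at least 20% of nuclei), from the authors' deposited table. The 2 respiratory genes under Fib (0.305) did not pass, and OPC held 0 ribosomal and 1 respiratory gene (0.738) in the authors' deposited table. Without genes listed under 4 or more labels, the ribosomal list still passed under Ast, Mic, Oli and End and the respiratory list under Ast and Mic. Over all labels, 30 of 80 ribosomal and 17 of 86 respiratory genes appear in the authors' deposited table, each of them on the first side wherever it was listed. Examples are Rpl41, with log2 fold changes from 0.29 to 0.55 under 6 labels, Ndufa4 (0.30 to 0.58, 6 labels), Cox5a (0.29 to 0.60, 4 labels) and Rps21 (0.28 to 0.46, 4 labels) in the authors' deposited table. None of the 47 genes was listed under Exn. Cck moved with them in the authors' deposited table, under Ast (0.35), Fib, Mic and Oli, and these 4 labels name cells whose Cck counts lay at the level common to all classes.

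**Figure D2:**
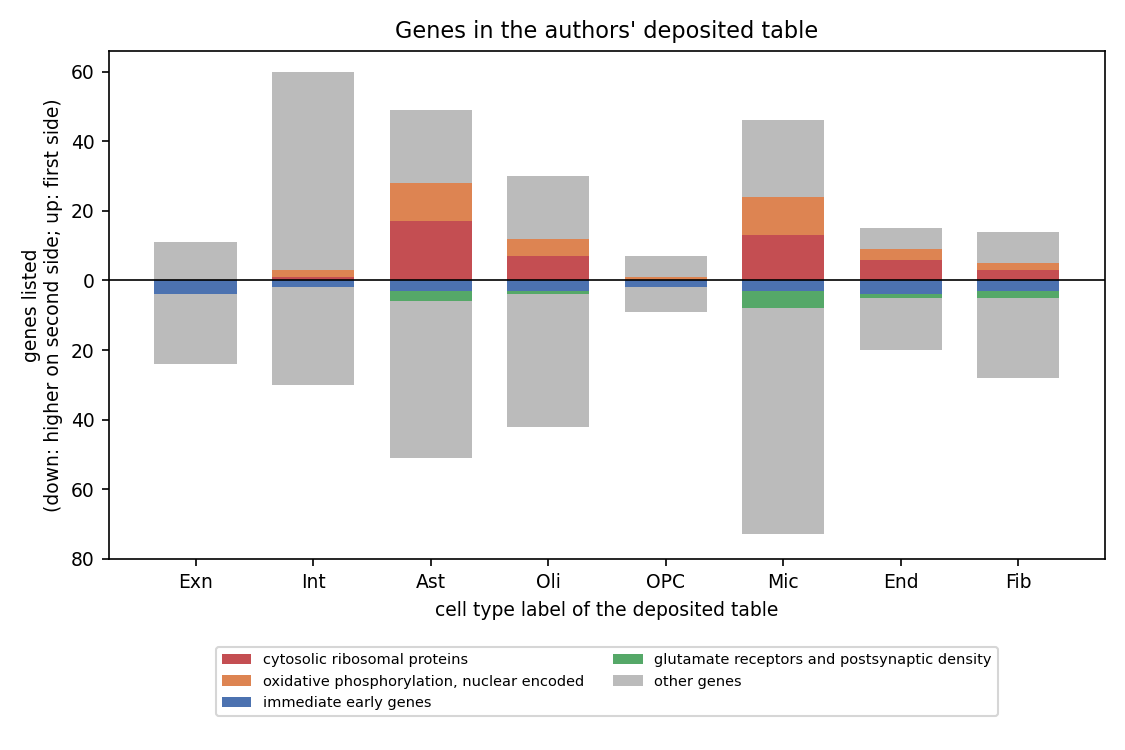
Genes in the authors' deposited table per cell type label, upward for genes higher on the first side and downward for genes higher on the second side. Colours mark members of 4 gene lists fixed before the data were examined, each gene counted once, and grey marks the rest. Ast shows 17 ribosomal and 11 respiratory genes upward, and Exn shows none.

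Immediate early genes were on the second side in glial and vascular labels too. Egr1 is listed under 7 labels of the authors' deposited table, with log2 fold changes from -0.65 to -0.25, Homer1 under 7 (-0.49 to -0.31) and Egr3 under 6 (-0.53 to -0.26). The list passed the test on the authors' deposited table under each of the 8 labels tied to a class, with adjusted p from 2.27e-06 under Exn to 0.00374 under Int. With a background of genes in at least 20% of nuclei the call under OPC was lost, and without genes listed under 4 or more labels the list passed under End only. All 6 members listed anywhere in the authors' deposited table, which also include Nr4a1 and Dusp1, were higher on the second side in every entry. Counts of Egr1 were alike in unlike cells, at 0.209 UMIs per nucleus in microglia-like, 0.213 in oligodendrocyte-like and 0.223 in astrocyte-like nuclei against 0.354 in excitatory-neuron-like nuclei. Under Mic, Ast and Fib, genes of glutamate receptors and the postsynaptic density were above chance on the second side of the authors' deposited table, with 6 of 19, 4 of 25 and 3 of 20 members (adjusted p = 0.000929, 0.0114 and 0.0125), and without genes listed under 4 or more labels under Mic only. Under Mic these include Dlg2 (-0.47), a scaffold of the postsynaptic density, and the receptor genes Grik2, Grin2a and Grm7 in the authors' deposited table, and Dlg2 was highest in excitatory-neuron-like nuclei.

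A small set of genes recurred under most labels. The authors' deposited table lists 294 different genes, of which 94 appear under 2 or more labels, and 90 of these keep to 1 side. Camk1d, a calcium-dependent kinase, and Cmss1 were higher on the second side under 8 labels, with log2 fold changes from -1.01 to -0.26 and from -0.82 to -0.39 in the authors' deposited table. Lars2, the mitochondrial leucyl-tRNA synthetase, was higher on the second side under 7 (-0.75 to -0.27) in the authors' deposited table. Pde10a, a cyclic nucleotide phosphodiesterase, differed most under Ast (-0.90), where it was found in 39.6% of nuclei on the first and 62.5% on the second side of the authors' deposited table. Between libraries, its detection in astrocyte-like nuclei ran from 14.3% to 78.8%. Il1rapl1 was listed on the first side under Int (0.27) and on the second under End, Fib and Mic in the authors' deposited table. It was 2.06-fold higher in the cluster of 2066 inhibitory-neuron-like nuclei described below. Without that cluster, the highest library value of Il1rapl1 in inhibitory-neuron-like nuclei was 3435 CPM instead of 5070. Whether the cluster gives its sign under Int was not tested.

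**Figure D3:**
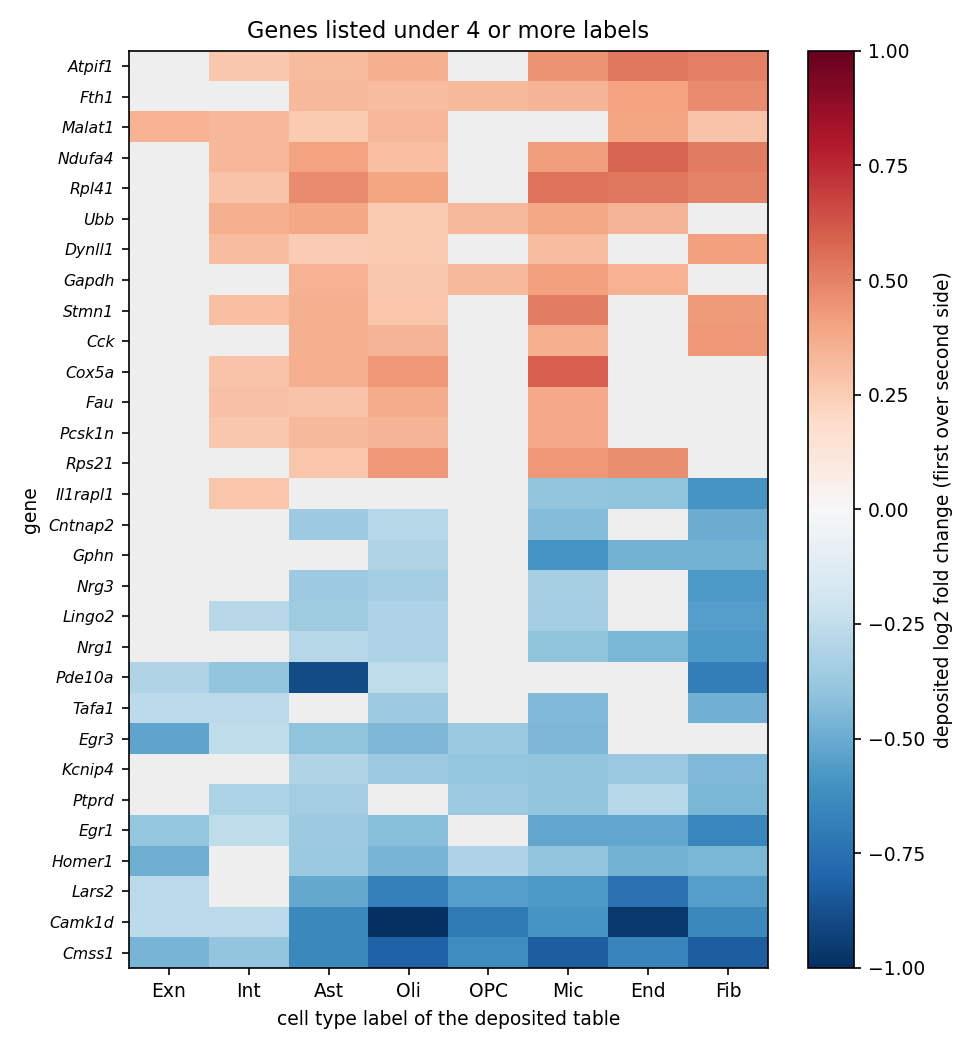
Log2 fold change of the first over the second side in the authors' deposited table for the 30 genes listed under 4 or more cell type labels. Light grey means that the gene is not listed under that label. Camk1d and Cmss1 are higher on the second side under 8 labels, and Il1rapl1 is the one gene with both signs.

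Inhibitory neurons had the most genes on the first side. The authors' deposited table lists 90 genes under Int, 60 of them higher on the first side, led by Meis2 (1.25), Tenm3 (1.11), Pbx3 (1.11) and Cpa6 (0.90). Meis2 and Pbx3 are homeobox genes of neuronal development. Meis2 was found in 29.8% and 18.5% of nuclei on the first and second side of the authors' deposited table, and between libraries its detection in inhibitory-neuron-like nuclei ran from 6.76% to 70.0%. A cluster of 2066 inhibitory-neuron-like nuclei, of which 77.5% carried suffix 14, had 48 of these 60 genes at 2-fold or more above the other inhibitory-neuron-like nuclei, against 1 of the 30 genes higher on the second side of the authors' deposited table. Those 30 genes were mostly lower in the cluster, with a median fold of 0.362. Reln (0.0611) and Gabrb2 (0.224) were among the lower ones. Uneven shares of this cluster between libraries can therefore bear on both sides.

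Most lists chosen for stress had few or no entries, but their absence is weak evidence. Every entry of the authors' deposited table reached at least 10.2% of nuclei on its higher side. On the first side, the background held 3 of 17 steroid and stress peptide genes under Ast, where 0.0501 would be listed by chance. It held 4 of 32 microglial activation genes under Mic (0.0963) and 22 of 24 astrocyte homeostasis genes under Ast (0.367). Of 26 glucocorticoid-induced genes, the authors' deposited table lists Fkbp5 under Mic, higher on the first side at 0.35, and Dusp1 under End, higher on the second side at -0.58. No member of the lists of steroid and stress peptide receptors and ligands, circadian clock, monoamine receptors, cholesterol synthesis, oligodendrocyte differentiation, microglial activation, interferon response, reactive astrocytes, astrocyte homeostasis or choroid plexus appears in the authors' deposited table, and the lists of mitochondrially encoded and haemoglobin transcripts had 0 members in the matrix. Heat shock, blood-brain barrier, perineuronal net and striatal lists had 1 member each there, namely Hspa8, Slco1c1, Reln and Pde10a. The homeostatic microglia list had Cst3, the GABA list Gabrb2 and Gphn, and the presynaptic release list 5 members under 4 labels, all on the second side of the authors' deposited table except Cst3. Neuropeptide genes were above chance on the first side under Oli (Cck, Npy and Pcsk1n, adjusted p = 0.000946) and Ast (Cck and Pcsk1n, 0.0468) in the authors' deposited table, and under neither without genes listed under 4 or more labels. Xist was higher on the first side under Mic (0.29) and Fib (0.37), and its antisense partner Tsix higher on the second under Int (-0.30), in the authors' deposited table. Overlapping antisense genes such as these share sequence, and whether the counting used strand is not given in the sources used here.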

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

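No paired analysis was possible because no nucleus could be tied to a sample, so replicate numbers could not be used. For the same reason the tests between groups were not run, nor were they with DESeq2 or its size factors, without a filter on low counts, with depth as a covariate, without genes open to free RNA, with a logit scale for shares, with fry or an estimated correlation for lists, with a replicate left out or with the replicate number as a term. The settings with highest doublet scores left out, a minimum of 1000 UMIs, cluster 16 left out, other list backgrounds, recurrent genes left out and library 14 left out were chosen after seeing the data. Shares and counts have no direction to change. The folds of Fkbp5 (fibroblast-like over microglia-like), Sgk1 (oligodendrocyte-like over OPC-like) and Gfap (astrocyte-like over fibroblast-like) kept theirs with all barcodes, resolution 0.5, a minimum of 1000 UMIs and the highest doublet scores left out. With all deposited barcodes 25 results stayed within their counting interval, with Leiden resolution 0.5 23 did and the border-macrophage-like and layer 6 intratelencephalic-like shares had no value, since no cluster met those names, without the highest 5% of doublet scores 18 did, and with a minimum of 1000 UMIs 15 did. The cause of the changes below was not tested. Depth limits the shares of classes with shallow nuclei, which a minimum of 1000 UMIs removes by construction: the oligodendrocyte-like and microglia-like shares fell, while the OPC-like share stayed within its interval.

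With all barcodes, unnamed clusters held 3.63% and layer 6 corticothalamic-like nuclei 14.9%. At resolution 0.5, Pvalb-like nuclei held 28.7% and Sst-like 20.02% of inhibitory-neuron-like nuclei. Without the highest doublet scores the pooled shares were 53.8% excitatory-neuron-like, 8.35% astrocyte-like, 8.27% oligodendrocyte-like, 5.54% microglia-like and 1.72% endothelial-like, with 32.8% layer 2/3, 15.9% layer 6 corticothalamic, 6.19% layer 6 intratelencephalic and 5.41% layer 5/6 near-projecting among excitatory-neuron-like nuclei. With at least 1000 UMIs they were 63.9% excitatory-neuron-like, 14.1% inhibitory-neuron-like, 7.88% astrocyte-like, 4.04% oligodendrocyte-like, 1.42% microglia-like, 2.59% unnamed, 1.44% fibroblast-like, 1.29% endothelial-like, 0.248% mural-like, 0.569% committed-precursor-like and 0.0472% border-macrophage-like, and the fold of Fkbp5 moved from 1.42 to 1.59. Among non-neuronal nuclei alone, by construction, astrocyte-like nuclei held 27.6%, oligodendrocyte-like 27.2%, microglia-like 18.3%, OPC-like 8.06%, fibroblast-like 7.45%, endothelial-like 6.24%, mural-like 2.67%, committed-precursor-like 1.72% and border-macrophage-like 0.775%. Without cluster 16, Pvalb-like nuclei held 33.3%, Sst-like 25.9% and Lamp5-like 17.0% of inhibitory-neuron-like nuclei.

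With each library left out in turn, the pooled shares ran from 53.9% to 55.2% (excitatory-neuron-like), 10.9% to 12.8% (inhibitory-neuron-like, lowest without suffix 14), 7.95% to 8.30% (astrocyte-like), 7.35% to 8.26% (oligodendrocyte-like), 5.18% to 5.48% (microglia-like), 3.35% to 3.96% (unnamed), 2.31% to 2.45% (OPC-like), 2.06% to 2.33% (fibroblast-like), 1.664% to 1.965% (endothelial-like), 0.721% to 0.819% (mural-like), 0.490% to 0.519% (committed-precursor-like) and 0.219% to 0.234% (border-macrophage-like). Among excitatory-neuron-like nuclei they ran from 31.9% to 33.2% (layer 2/3), 14.96% to 15.63% (layer 6 corticothalamic), 6.99% to 7.22% (layer 6 intratelencephalic), 5.14% to 5.94% (layer 5 extratelencephalic), 5.13% to 5.33% (layer 5/6 near-projecting) and 0.526% to 0.600% (layer 6b), and among inhibitory-neuron-like nuclei from 26.6% to 31.4% (Pvalb-like), 20.6% to 24.5% (Sst-like) and 13.6% to 16.5% (Lamp5-like).

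Of the 23 list tests called on the authors' deposited table, 9 were called when genes listed under 4 or more labels were left out, and all 9 are among the 23. These were the ribosomal list under Ast, Mic, Oli and End, the respiratory list under Ast and Mic, immediate early genes under End, neurotrophin genes under Exn and glutamate receptor genes under Mic. The other calls, among them immediate early genes under the 7 other labels, were lost, which recurrent genes bring about by construction. With a background of genes in at least 5% of nuclei 25 were called, the 23 with neuropeptides (first side) and presynaptic release (second side) under Mic. With 20% of nuclei 21 were, without the ribosomal list under Fib and immediate early genes under OPC. Without library 14, 46 of the 60 Int genes were 2-fold higher in cluster 16, against 48. Random draws from genes in at least 20% of nuclei gave up to 63 genes under 2 or more labels, against 41 with the background used and 94 observed.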

Other observations

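A group of inhibitory-neuron-like nuclei led by Pbx3, Lgr5, Adamts19 and Cpa6 came mostly from 1 library. It was 67.0% of the inhibitory-neuron-like nuclei of suffix 14, 41.6% of suffix 21, 4.38% of suffix 20, 1.75% of suffix 16 and 1.38% of suffix 18, and under those shares in the other 7, with 0 nuclei at suffix 15. A cluster of 725 excitatory-neuron-like nuclei led by Ndst4, Abi3bp and Tfap2d, a transcription factor, was 6.78% of all kept nuclei of suffix 14 and at most 0.698% of any other library. Layer 5 extratelencephalic-like nuclei were 0.184% of excitatory-neuron-like nuclei at suffix 12, 0.983% at suffix 23, 1.99% at suffix 18 and between 3.84% and 8.83% in the others. The labels give no group for these libraries, and no biological explanation was tested for them.

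Libraries fell into separate clusters on the summed CPM of Cmss1, Camk1d and Lars2. In oligodendrocyte-like nuclei the sums were 504, 492, 515, 455, 670 and 463 for suffixes 12, 13, 14, 15, 16 and 17, and 1169, 1238, 1224, 1215, 1127 and 1210 for suffixes 18, 19, 20, 21, 22 and 23. The widest gap between neighbouring values parted the same libraries in 8 of 10 classes examined, and fell elsewhere in inhibitory-neuron-like and committed-precursor-like nuclei. In all 10 classes the sums of suffixes 12 to 17 lay below those of suffixes 18 to 23. Each of these sets held 6 libraries, the size of each of the 2 groups in the labels. In the authors' deposited table Cmss1 and Camk1d were higher on the second side under 8 labels, and Lars2 under 7. If the split were that of the groups, the upper libraries would lie with the second side. No label gives the group of a suffix, so whether the split follows the groups or another difference between libraries was not tested.

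The tests on cluster 16, on respiratory genes under Exn, on ratios to Cck and on the rise of free Malat1 were chosen only after the result was seen. The tests by correlation were planned over all 12 libraries and first computed so. There, the sum of recurrent first-side genes against Cck and the correlation among Cmss1, Camk1d and Lars2 came out undecided, and that of neuronal genes came out above its bound. Their form within the 2 clusters of 6 libraries was chosen after those values and the clusters had been seen, because a correlation across separate clusters mostly reflects the gap between them. The 78 correlations computed within clusters rest on 6 libraries each, and none passed adjustment (lowest adjusted p 0.217). The 92 values for neuronal genes rest on 6 libraries each as well and carry no p-value. A median of such correlations was counted for or against an explanation only where every value behind it lay beyond the bound, including those computed without the 2 libraries farthest from the median. That condition was added after the medians had been seen, and none of the 4 medians met it. By the bounds alone, -0.166 and 0.157 would count against the explanations they test, and 0.767 would count for its own. So would 0.922, the median for the recurrent first-side genes without Malat1, a sum chosen after the data were seen.

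Of the 60 Int genes higher on the first side of the authors' deposited table, 80% were at least 2-fold higher in the Pbx3 and Lgr5 cluster than in other inhibitory-neuron-like nuclei, against 4.41% of the 4765 background genes. Without the cluster, the range of these genes between libraries shrank to a median of 0.161 of its size, against 0.682 for the genes of the second side. That shrinkage follows largely from the folds and the uneven spread of the cluster over libraries, so it adds no separate support. A candidate explanation, from the folds, is cells of another type, held mostly by 1 library. Libraries differ in how many nuclei of this cluster they hold. This would bear on the genes of the second side too, whose median fold in the cluster was 0.362. No label gives the side of a library. By the split on Cmss1, Camk1d and Lars2, suffix 14 lay with the lower libraries and suffix 21 with the upper. An effect of stress on these neurons was not tested and stays open.

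The genes higher on the first side under 4 or more labels of the authors' deposited table could in part be free RNA from broken cells. Malat1, 84.0% of their sum, does not decide whether free RNA is their whole cause. In 3 glial classes 0 of its 36 ratios to Cck lay within 1.5-fold of the ratio in excitatory-neuron-like nuclei (0.125 to 0.589). That shows only that excitatory-neuron-like nuclei hold more Malat1 per Cck. If free RNA brings no more Malat1 per Cck than microglia-like nuclei hold, the fold changes of Malat1 need a log2 rise of its free part. Those under Exn and Int need at least 0.77, that under Ast at least 0.631 and that under End at least 0.665. The one under Oli needs 0.497 to 0.616 and the one under Fib 0.510 to 1.135. The other genes of the set reached at most 0.60 in the authors' deposited table. By the rule written for this test, the values under Exn and Int would count against free RNA. The 0.60 is no ceiling for free RNA, however, since transcripts of the cell's own can lower a fold change. The median r of the sum with Cck in the 3 glial classes was -0.166 (from -0.372 to 0.0549), under its bound. Without the 2 farthest libraries of each cluster the values ran from -0.794 to 0.514. For the genes other than Malat1, the median r with Cck was 0.922 (from 0.752 to 0.967, and from 0.0448 to 0.899 without the 2 farthest libraries). In the 3 glial classes 98.4% of 432 ratios to Cck lay within 1.5-fold, against 12.99% for 2507 other genes. Such ratios are what free RNA would give, but none were taken in vascular nuclei. In endothelial-like nuclei Rpl41 had 0.822 and Cck 0.777 UMIs per nucleus, against 0.422 and 0.962 in excitatory-neuron-like nuclei. Rpl41 thus did not keep its ratio to Cck there. A change of ribosomal and respiratory genes within every cell type cannot be told apart from other causes. Exn lists 0 where 12.8 would be listed at the rate of the other labels but only 4.08 at their share of a list. Free Malat1 and an effect of stress stay open.

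The genes higher on the second side under 4 or more labels of the authors' deposited table were set against 3 explanations. For the neuronal genes among them, free neuronal RNA cannot be told apart from other causes. In glial and vascular nuclei the median r of each gene with the sum of the others was 0.767, above the bound of 0.5. The 92 values ran from -0.458 to 0.997. Reads of ribosomal RNA assigned to Cmss1, Camk1d and Lars2 cannot be told apart from other causes: the median r among these genes within clusters was 0.157, under the bound of 0.3, but the 60 values ran from -0.748 to 0.907. Chance overlap of the lists is argued against, over both sides: 30 genes stood under 4 or more labels and at most 1 did in 1000 random draws, and 94 stood under 2 or more and at most 41 did, and an effect of stress stays open.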
